A study of Mus musculus with 130 samples.

How the data were processed

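RNA was measured by sequencing in sorted and unsorted cells of FVB/NJ mouse embryos that carry the FUCCI reporter, at E10.5, E11.5 and E13.5. Per the labels' protocols, embryos were minced and sorted by flow, total RNA was purified with a column kit, ribosomal RNA was depleted and libraries were built with standard Illumina methods. The kit, and whether it marks strand, are not given in the sources used here. The authors deposited 1 table of raw counts, whole numbers of reads per gene for 130 columns, with no normalization. Per the submitters' processing notes the tools were STAR 2.5.3 and HTSeq 0.8.0 and the genome build was mm10. Whether reads were counted by strand, and which annotation was used, are not given in the sources used here. The table held 52550 genes, of which 41706 had a count, and 0 of its entries named no gene. For 185 genes the symbol was shared with another gene, and these were kept apart by their identifier. Locations and strand overlaps came from GENCODE M21 on GRCm38, the assembly that mm10 names, where 52403 identifiers matched and 48050 of these had the same symbol.

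Titles that differ in their last number within a preparation and fraction were parts of 1 library. Over genes with an expected count of at least 5, the index of dispersion between such parts was 1.09 to 1.23 (median 1.15), under the limit of 1.5 set beforehand, while between preparations of 1 fraction and day it was 5.9 to 117.5. The counts were therefore summed to 25 libraries, and each library was counted once in n. Library totals were 14.7 to 58.5 M counts (M for mega) with a median of 22.9 M. A gene at 0 in a library could have up to 3 counts expected there, and such limits cover counting error only. The replicate was the preparation (WT1, WT2, WT3, 5 and 8), and fractions came from the phase label of each sample.

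Tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15, grouped by fraction), scaled by TMM factors and tested by the quasi-likelihood F test with robust dispersion, with Benjamini-Hochberg adjustment and a threshold of 0.05. The phase comparisons and the comparison of sorted with unsorted cells came from 1 model of all 25 libraries with fraction and embryonic day as terms. The comparison of days used the 5 unsorted libraries, and the day difference used a mean for each day and fraction. Standard errors are the absolute log2 change divided by the square root of F. CPM values are counts scaled to the TMM-adjusted library total. Levels on a log2 scale had 0.5 added to each count.

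The 24 gene lists were fixed before the data were examined and cover the cell cycle, cell types that a gate could hold, the response to dissociation, ribosomal protein genes and mitochondrially encoded genes. They were tested with camera at a preset correlation of 0.01 in 7 comparisons, which made 168 tests adjusted together, and again with an estimated correlation. Some members were not tested in the phase comparisons: Cdkn2a among the CDK inhibitors, Hbb-b1, Hbb-b2 and Ahsp among the erythroid genes, Snorc among the cartilage genes, and Apoa4, Apoc2 and Apoh among the hepatocyte genes. The genes named in the text were set by a rule: the 5 highest and 5 lowest log2 changes past the test with a mean log2 CPM of at least 3 and the same direction in each preparation, leaving out predicted genes and small RNA genes, then up to 2 members each way of each list with at least 5 members that passed its test, and the E2F, cyclin, CDK inhibitor, licensing and Lin28 genes fixed by name. Other genes are named where a count is small, and were then chosen after their values were seen.

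Whether libraries of 1 preparation deviate together was checked by correlating, between fractions, the difference between the preparations of a day over 11173 genes, which gives the same value as the deviations from the group means. The correlations were 0.12 to 0.741 at E10.5 and 0.308 to 0.661 at E13.5, all over 0.1. The main tests had no term for the preparation and did not pair the fractions by it, and a block for the preparation was an alternative. Without Xist, Tsix and the genes of chromosome Y, the lowest correlations were 0.119 and -0.143. The pairing itself comes from the title prefix, and the labels do not say what a prefix stands for.

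The tests were tried on simulated counts with the real library sizes and a small random set of genes changed. The means were those of each day, or 1 mean over all days for the comparison of days, without differences between fractions. Libraries were drawn independently, without a preparation effect, and far fewer genes changed than were called in the real data. The recovered and false shares may therefore not hold for the real data. For S-G2-M against G0 over 23185 genes, 25.4% of genes changed by 1.5-fold, 58.2% of those changed by 2-fold and 77.3% of those changed by 4-fold were recovered, and 5.3% of the calls were false. For the comparison of days over 23196 genes the recovered shares were 0%, 1.5% and 56.1%, with 5% of the calls false. For the day difference over 23217 genes they were 1.5%, 4.5% and 34.8%, with 3.6% of the calls false.

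The alternatives fixed before the data were examined were DESeq2 1.42.0 with its size factors, RLE factors, no filter on low counts, abundant genes left out, equal depth, parts of libraries not summed, preparation as a block, the WT-titled preparations or preparations 5 and 8 alone, sorted libraries alone, a 2-fold minimum, each preparation left out in turn, and for the days the sorted fractions summed or a mean for each day and fraction. Added after the data were seen were genes without a gene body on the other strand, Gm26917 and Gm42418 left out, and the unsorted library of WT3 left out. Overlaps were computed with bedtools 2.31.1, and figures were drawn with matplotlib 3.10.9. Results for a few genes, among them 2 of the 41 flagged for a day difference, are not reported here.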

Results

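The series measured RNA of FVB/NJ mouse embryos that carry FUCCI, a fluorescent reporter in which red marks cells before S phase and green marks cells from S phase to mitosis. Embryos of E10.5, E11.5 and E13.5 were minced and sorted into 4 gates, which the labels assign to G0 (BR), G1 (DR), G1-S (YE) and S-G2-M (GR), beside unsorted cells (US). The design asks how expression differs between these phases over 3 embryonic days, and the title of the series names the E2F transcription factors. The 130 deposited samples were parts of 25 libraries, from 5 preparations with 5 fractions each. Preparations WT1 and WT2 were of E10.5, WT3 of E11.5, and 5 and 8 of E13.5. Each fraction had n = 5 preparations over all days. The labels do not say whether a preparation was 1 embryo or a pool. In the comparison of days, with 1 library per preparation, p-values measure the spread between preparations. In the phase comparisons and that of sorted with unsorted cells they measure the residual spread of all 25 libraries. In the day difference they measure the spread within the E10.5 and E13.5 libraries, because each E11.5 library has its own mean. In all but the comparison of days, the 5 libraries of a preparation counted as independent, although their deviations were correlated. In the phase comparisons that spread also holds differences of the phase change between days. Library totals ran from 15.6 to 49.0 M counts at E10.5, from 17.3 to 58.5 M at E11.5 and from 14.7 to 29.2 M at E13.5, with a median of 22.9 M. Mitochondrially encoded genes took 0.372% to 0.701% of the counts in the WT-titled libraries and 1.66% to 3.42% in those of preparations 5 and 8.

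Cells of the G1 gate were set against those of the G0 gate to ask what separates the red gates. Most neuronal genes were lower in G1 and most genes of DNA replication were higher. With an estimated correlation these list calls were lost (adjusted p = 0.0724 for neuronal genes, 0.0546 for licensing, 0.098 for DNA synthesis and 0.0724 for recombination). Of 24 neuronal genes, 22 fell and none rose (also 22 adjusted over the list alone; median log2 change -2.65). Nefl, a neurofilament subunit, fell by 4.32 ± 0.53 on the log2 scale (SE, n = 5 preparations, adjusted p = 1.2e-06) and Mapt, the tau protein, by 4.06 ± 0.43. Outside that list Robo3, an axon guidance receptor, fell by 4.10 ± 0.72. Robo3 (ENSMUSG00000032128.15, chromosome 9 from 37415669 to 37433246, minus strand) stood at 661 ± 388 CPM in G0 (mean ± SD, n = 5) and at 38.4 ± 31.5 CPM in G1. Prph, a neuronal intermediate filament, changed by -5.11 ± 0.58. Conversely 21 of 23 replication licensing genes rose (22 adjusted over the list alone), led by Mcm10 (1.84 ± 0.18) and Cdc6 (1.71 ± 0.18). DNA synthesis genes rose in 30 of 31 cases (30 adjusted over the list alone), with Rrm2, a subunit of ribonucleotide reductase, at 1.89 ± 0.19, and all 19 genes of homologous recombination and crosslink repair rose, with Exo1 at 1.68 ± 0.20. All 9 G1 cyclin and kinase genes rose, Ccnd1 by 1.75 ± 0.17 and Ccne1 by 1.59 ± 0.17. Adjusted over the list alone, the counts of these last lists were 19 and 9. Of 39 G2/M genes 32 rose and 1 fell (34 and 1 adjusted over the list alone, adjusted p = 0.486 with an estimated correlation). The gene that fell was Racgap1, a regulator of cytokinesis (-1.09 ± 0.18). Histone genes rose in 34 of 66 cases and fell in 4 (36 and 4 adjusted over the list alone, adjusted p = 0.712 with an estimated correlation). Their list mean, the mean log2 CPM of the members, rose from 1.206 to 2.387 in WT1 and from 1.817 to 2.764 in WT2, moved little in WT3 (1.954 to 2.094) and preparation 5 (2.441 to 2.622) and was lower in 8 (2.695 to 2.49). Hist1h3g was at 1.52 ± 0.30 and Hist3h2a at -2.20 ± 0.22. The G1 cyclin list kept its call with an estimated correlation (adjusted p = 0.0158).

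The same contrast separated marker genes of several cell types. Neural progenitor genes rose in 14 of 16 cases (15 adjusted over the list alone, adjusted p = 0.29 with an estimated correlation), among them Hes5, a target of Notch signalling (2.66 ± 0.32). Mesenchyme and matrix genes rose in 20 of 21 cases (20 adjusted over the list alone, adjusted p = 0.345 with an estimated correlation). Twist1 was at 1.73 ± 0.34 and Prrx1 at 1.69 ± 0.39. Macrophage genes rose in 14 of 16 cases (14 adjusted over the list alone, adjusted p = 0.0724 with an estimated correlation), including Mrc1, the mannose receptor (2.69 ± 0.18), and C1qb (2.65 ± 0.42). Erythroid genes rose in 13 of 19 cases (14 adjusted over the list alone, adjusted p = 0.414 with an estimated correlation), with Hba-x at 3.69 ± 0.46 and Hbb-y at 3.43 ± 0.44; globin genes have similar copies that can share reads. The list mean rose from 0.94 to 4.881 in WT1 and less in the others, from 1.931 to 2.584 in WT2, 2.303 to 3.486 in WT3, 3.482 to 4.222 in preparation 5 and 3.138 to 4.521 in 8, and without WT1 the values were 2.98 for Hba-x and 2.76 for Hbb-y. Epithelial genes rose in 11 of 15 cases (12 adjusted over the list alone, adjusted p = 0.486 with an estimated correlation). Krt14 was at 2.25 ± 0.35. Of 13 cartilage genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.345 with an estimated correlation). Their list mean rose in preparations 5 (6.051 to 8.113), 8 (5.801 to 7.951) and WT1 (2.949 to 3.494), stayed at 3.709 in WT2 and fell in WT3 (3.862 to 3.497). Col9a1 rose by 2.0 ± 0.20, while Cnmd was lower by 2.65 ± 0.79 over all days but rose by 2.27 in preparations 5 and 8. Of 18 cardiac genes 10 fell and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.755 with an estimated correlation). Their list mean fell only in WT1 (2.666 to 1.046), WT2 (3.94 to 2.199) and WT3 (3.724 to 1.938), and was higher in G1 in preparations 5 (0.742 to 0.901) and 8 (1.062 to 1.241). Myh7, a myosin heavy chain, was at -2.75 ± 0.70. Of 85 ribosomal protein genes 57 rose (66 adjusted over the list alone, adjusted p = 0.486 with an estimated correlation), with Rpsa at 0.87 ± 0.15. Of 22 dissociation response genes, which respond to handling of tissue, 10 rose and 1 fell (10 and 2 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation). Socs3 was at 1.0 ± 0.19 and Dusp1 at -0.50 ± 0.15. Over all genes 4285 were higher in G1 and 4255 lower, of 23506 tested (edgeR quasi-likelihood test, adjusted p under 0.05). At a 2-fold minimum 39.3% of the calls were higher, against 50.2%. Within the WT-titled preparations 6490 genes changed, and within preparations 5 and 8 it was 9029. Cnmd did not pass the test without WT1 (adjusted p = 0.116), WT2 (adjusted p = 0.143) or WT3 (adjusted p = 0.121), and Myh7 stood at -0.51 in preparations 5 and 8 (adjusted p = 0.561).

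The G1-S gate was set against the G1 gate to ask what is higher in the yellow gate. Of the cell cycle lists, those of replication-dependent histone genes and of mitotic genes had the largest median rise. Of the sorted fractions, S-G2-M had the highest mean level for 38 of 39 G2/M genes and 58 of 66 histone genes. For 20 of 23 licensing genes it was G1-S. Pairs of a red and a green cell sorted together could also give a level between G1 and S-G2-M, which was not tested for these lists. Histone genes rose in 65 of 66 cases (65 adjusted over the list alone; median log2 change 3.79, against 2.94 for G2/M genes), and the call held with an estimated correlation (adjusted p = 0.00037). Hist1h2af rose by 4.71 ± 0.27 (SE, n = 5; adjusted p = 2.59e-11), from 2.34 ± 2.38 CPM to 82.0 ± 97.5 CPM (mean ± SD, n = 5), and Hist1h2ah by 4.41 ± 0.28. Histone genes have near-identical copies, so reads can be divided among them, and 35.3% of the exon length of Hist1h2af lies under exons of the other strand. G2/M genes rose in 38 of 39 cases (38 rose and 1 fell adjusted over the list alone), with the kinesin gene Kif11 at 3.88 ± 0.25, Aurkb at 3.71 ± 0.28 and Ccnb1, cyclin B1, at 3.65 ± 0.30. Every gene of the licensing (23), DNA synthesis (31) and recombination (19) lists rose, with the same counts adjusted over the list alone, including Cdc45 at 2.06 ± 0.18, Rrm2 at 2.13 ± 0.19 and Fancd2 at 2.47 ± 0.16. These 4 calls held with an estimated correlation (adjusted p = 0.0038 for G2/M, 0.0109 for licensing, 0.0109 for DNA synthesis and 0.00184 for recombination). Of 9 G1 cyclin and kinase genes 5 rose (6 adjusted over the list alone, adjusted p = 0.109 with an estimated correlation). Ccne2 was at 2.11 ± 0.17 and Ccne1 at 1.72 ± 0.16. Among single genes, Gmnn, geminin, rose by 1.76 ± 0.19 and Cdt1, its partner in licensing control, by 0.88 ± 0.12. Neuronal genes fell in 10 of 24 cases (11 adjusted over the list alone, adjusted p = 0.524 with an estimated correlation), led by the early neuronal factors Nhlh2 (-2.23 ± 0.37) and Nhlh1 (-2.22 ± 0.35). The neuronal list mean fell only in WT1 (5.818 to 4.205), WT2 (5.475 to 4.451) and WT3 (5.317 to 3.881), and rose in preparations 5 (4.357 to 4.457) and 8 (4.314 to 4.847). Scrt2, a neuronal repressor, fell by 3.18 ± 0.58. Neural progenitor genes fell in 5 of 16 cases (1 rose and 6 fell adjusted over the list alone, adjusted p = 0.679 with an estimated correlation). This list mean too fell only in WT1 (6.052 to 5.18), WT2 (5.839 to 4.91) and WT3 (5.539 to 4.911), and rose in preparations 5 (5.077 to 5.209) and 8 (5.115 to 5.467). Neurog2 was at -1.83 ± 0.41 and Dll1 at -1.52 ± 0.27.

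Part of the genes of other cell types rose at the same step. All 14 hepatocyte genes rose (14 adjusted over the list alone, adjusted p = 0.368 with an estimated correlation). Their median log2 change, 4.15, was the largest of all lists. Apoa2 was at 5.78 ± 0.99 and Afp, alpha-fetoprotein, at 4.38 ± 0.93. The rise was larger at E13.5: the list mean went from -0.088 to 6.481 in preparation 5 and from -0.389 to 6.091 in 8, but from -1.077 to 0.255 in WT1, from -0.27 to 0.45 in WT2 and from 0.479 to 1.978 in WT3. Macrophage genes rose in 15 of 16 cases (15 adjusted over the list alone, adjusted p = 0.0285 with an estimated correlation). C1qa was at 2.68 ± 0.27 and Adgre1 at 2.54 ± 0.32. Cardiac genes rose in 15 of 18 cases (17 adjusted over the list alone, adjusted p = 0.203 with an estimated correlation). Myl2 was at 4.61 ± 0.63 and Myh7 at 4.37 ± 0.74. Endothelial genes rose in 2 of 15 cases (13 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation), Egfl7 by 1.22 ± 0.31. Erythroid genes fell in 1 of 19 cases (0 adjusted over the list alone, adjusted p = 0.705 with an estimated correlation), which was Hba-x (-1.29 ± 0.42; -1.20 with adjusted p = 0.0522 when preparation was a block, and -0.72 with adjusted p = 0.228 without WT1). The erythroid list mean was higher in G1-S in WT2 (2.584 to 2.815) and preparation 5 (4.222 to 4.336). Ribosomal protein genes rose in 10 of 85 cases (8 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation), with a lower list mean in WT2 (6.158 to 5.886). Over all genes 2757 rose and 1687 fell, so that 62.0% were higher, against 51.9% higher with RLE factors, 50.3% with DESeq2 and 50.1% with Gm26917 and Gm42418 left out, an alternative chosen after the data were seen. It was 69.9% at a 2-fold minimum and 49.2% without preparation 8. The count was 4444 in all, 2233 within the WT-titled preparations and 8476 within preparations 5 and 8, and it was 2529 without preparation 5 and 2768 without preparation 8.

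**Figure D1:**
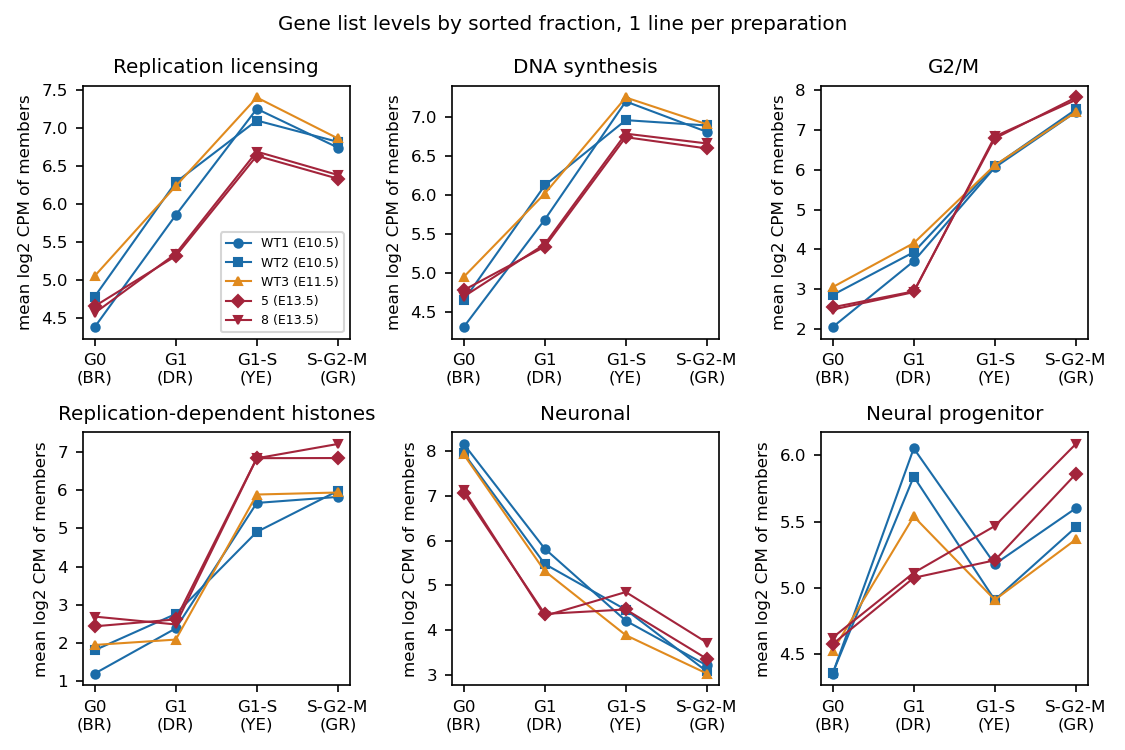
Mean log2 CPM of the members of 6 gene lists (vertical axes) in the 4 sorted fractions (horizontal axes), 1 line per preparation, coloured by embryonic day. Mitotic and histone genes step up between G1 and G1-S in each preparation, while neuronal genes are highest in G0.

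The S-G2-M gate was compared with G1-S to ask how the green gate differs from the yellow one. Most mitotic genes rose further and 12 of 23 replication licensing genes fell back, and neither list kept its call with an estimated correlation. G2/M genes rose in 38 of 39 cases and Mybl2 fell (38 and 1 adjusted over the list alone, adjusted p = 0.0882 with an estimated correlation). Ube2c, a ubiquitin conjugating enzyme of mitotic exit, rose by 1.90 ± 0.29 (SE, n = 5; adjusted p = 0.000135), Ccnb1 by 1.67 ± 0.27 and Plk1, a mitotic kinase, by 1.65 ± 0.24. Pif1, a DNA helicase, rose most among the genes named by rule, by 2.0 ± 0.33. Licensing genes fell in 12 of 23 cases and rose in 1 (14 and 1 adjusted over the list alone, adjusted p = 0.37 with an estimated correlation). Cdc6 fell by 1.77 ± 0.18, Cdt1 by 0.85 ± 0.12 and Mcm2 by 0.45 ± 0.10, while Dbf4, the activator of the Cdc7 kinase, rose by 0.72 ± 0.13. DNA synthesis genes fell in 7 of 31 cases (10 adjusted over the list alone, adjusted p = 0.713 with an estimated correlation), Chaf1b by 0.72 ± 0.16. G1 cyclin and kinase genes fell in 2 of 9 cases (3 adjusted over the list alone, adjusted p = 0.575 with an estimated correlation), Ccne2 by 1.71 ± 0.17 and Ccne1 by 0.76 ± 0.16. Histone genes rose in 2 of 66 cases (0 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation), which were Hist1h4c (0.75 ± 0.25) and Hist1h2bh (0.69 ± 0.20). Without WT2 neither passed (adjusted p = 0.216 for Hist1h4c and 0.0993 for Hist1h2bh). Of the CDK inhibitors, Cdkn1a was lower by 1.5 ± 0.30 and Cdkn1c by 0.87 ± 0.24, and Cdkn1b was higher by 0.65 ± 0.10. Neural progenitor genes rose in 8 of 16 cases (8 rose and 1 fell adjusted over the list alone, adjusted p = 0.33 with an estimated correlation), with Sox1 at 1.44 ± 0.17. Neuronal genes fell in 13 of 24 cases (16 adjusted over the list alone, adjusted p = 0.306 with an estimated correlation). Cntn2, a neuronal adhesion protein, was at -2.46 ± 0.44.

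Most macrophage, cardiac and hepatocyte genes, which had risen in G1-S, were lower again in S-G2-M. Macrophage genes fell in 15 of 16 cases (15 adjusted over the list alone) and the call held with an estimated correlation (adjusted p = 0.00022), with C1qa at -4.83 ± 0.31 and Mrc1 at -3.57 ± 0.18. Cardiac genes fell in 17 of 18 cases and Tbx5 rose (17 and 1 adjusted over the list alone, adjusted p = 0.0384 with an estimated correlation). Myh6 was at -5.41 ± 0.80 and Myl4 at -4.46 ± 0.56. All 14 hepatocyte genes fell (14 adjusted over the list alone, adjusted p = 0.323 with an estimated correlation), with Ahsg at -4.40 ± 1.19, lower in 3 of 5 preparations, and at -3.08 without preparation 5 (adjusted p = 0.138). The list mean in S-G2-M was 0.604 and 0.953 in preparations 5 and 8 and -0.042, 0.059 and 0.395 in WT1, WT2 and WT3. Endothelial genes fell in 13 of 15 cases (14 adjusted over the list alone, adjusted p = 0.35 with an estimated correlation), with Cldn5, a tight junction protein, at -1.93 ± 0.55 (-1.69 with adjusted p = 0.0971 without WT3). Erythroid genes fell in 9 of 19 cases (12 adjusted over the list alone, adjusted p = 0.196 with an estimated correlation). Hbb-y was at -3.26 ± 0.44. Skeletal muscle genes fell in 9 of 20 cases (12 adjusted over the list alone, adjusted p = 0.323 with an estimated correlation). Ttn, titin, was at -3.44 ± 0.67. Epithelial genes fell in 4 of 15 cases (6 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation), with Krt18 at -1.64 ± 0.35, and mesenchyme genes in 8 of 21 (2 rose and 13 fell adjusted over the list alone, adjusted p = 0.652 with an estimated correlation). Col6a1 was at -1.01 ± 0.22. Of the Lin28 and let-7 list 5 of 10 genes rose (7 adjusted over the list alone, adjusted p = 0.203 with an estimated correlation), with Mycn at 0.73 ± 0.14, and of 85 ribosomal protein genes 2 rose (0 adjusted over the list alone, adjusted p = 0.803 with an estimated correlation). The list mean did not rise in preparation 5 for the former (5.957 to 5.944) or in WT3 for the latter (6.535 to 6.441). Of the dissociation response genes 3 fell and none rose (7 adjusted over the list alone), a list that passed its test only when preparation was a block (adjusted p = 0.0629, 0.0192 with the block and 0.712 with an estimated correlation). Over all genes 1711 were higher and 2376 lower, so that 41.9% were higher. The share was 12.6% at a 2-fold minimum (196 of 1559), 30.7% with no filter on low counts and 50.5% without WT3. The count of 4087 was 2708 within the WT-titled preparations and 4914 within preparations 5 and 8, and it was 2653 without WT2 and 2430 without preparation 5.

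**Figure D2:**
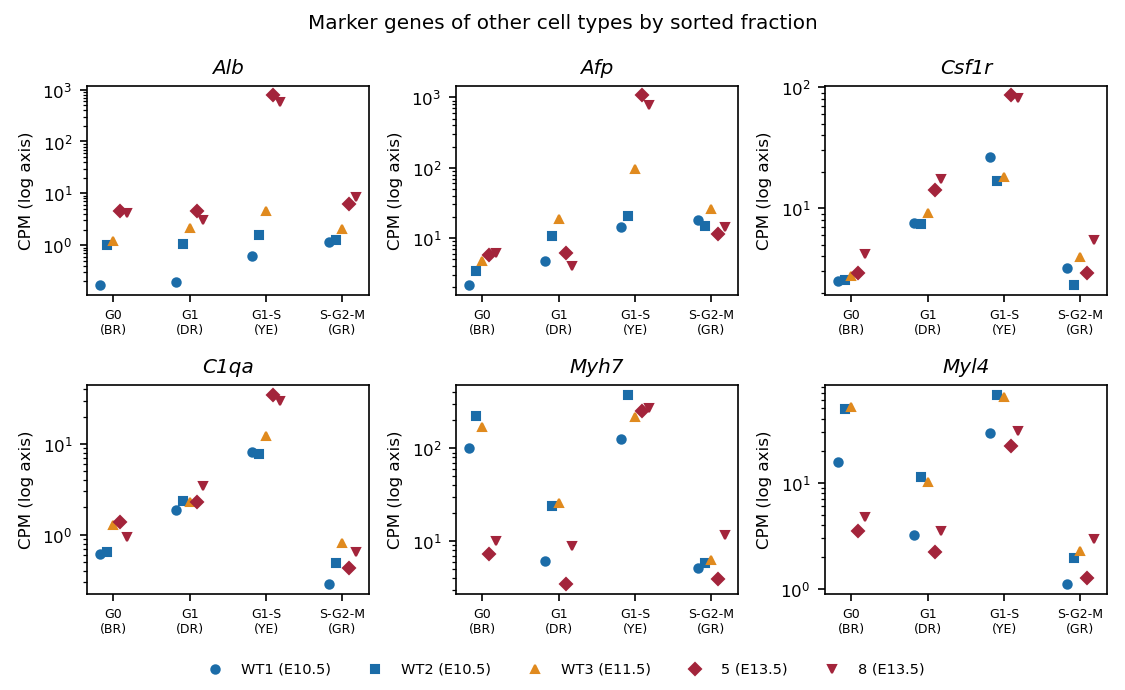
CPM on a log axis (vertical) of hepatocyte (Alb, Afp), macrophage (Csf1r, C1qa) and cardiac (Myh7, Myl4) genes in the 4 sorted fractions (horizontal), 1 point per preparation. In preparations 5 and 8 Alb averages 673 CPM in G1-S and 7.34 CPM in S-G2-M.

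The ends of the cycle, S-G2-M against G0, gave the most changed genes among the phase comparisons. All 39 G2/M genes rose (39 adjusted over the list alone; median log2 change 5.10, adjusted p = 0.019 with an estimated correlation). Ccnb1 (ENSMUSG00000041431.16, chromosome 13 from 100778650 to 100786570, minus strand) rose by 6.16 ± 0.34 (SE, n = 5; adjusted p = 8.73e-13), from 3.53 ± 1.23 CPM to 249 ± 24.7 CPM (mean ± SD, n = 5). Iqgap3, a scaffold protein of the cell cortex, rose by 6.18 ± 0.33, Hmmr by 6.13 ± 0.34, Ccna2 by 5.10 ± 0.26 and Mki67, the Ki-67 protein, by 5.65 ± 0.35. Histone genes rose in 65 of 66 cases and Hist3h2a fell (65 and 1 adjusted over the list alone, adjusted p = 0.019 with an estimated correlation). All 23 licensing, 31 DNA synthesis, 19 recombination and 9 G1 cyclin genes rose, with the same counts adjusted over the list alone and with Ticrr at 3.60 ± 0.19, Rrm2 at 3.68 ± 0.20, Fancd2 at 4.55 ± 0.18 and Cdk2 at 2.15 ± 0.17. Those 4 calls held with an estimated correlation (adjusted p = 0.0344, 0.0344, 0.0109 and 0.0351 in the same order). All 24 neuronal genes fell (24 adjusted over the list alone, median -4.36, adjusted p = 0.0724 with an estimated correlation), Ina, alpha-internexin, by 6.93 ± 0.60, Cntn2 by 6.63 ± 0.52 and Stmn2 by 6.09 ± 0.45. Outside that list Robo3 fell by 7.02 ± 0.85. Scrt1, a neuronal repressor, changed by -5.92 ± 0.45. Neural progenitor genes rose in 12 of 16 cases (12 adjusted over the list alone, adjusted p = 0.386 with an estimated correlation). Hes5 was at 3.32 ± 0.32 and Sox3 at 2.41 ± 0.24. Ribosomal protein genes rose in 81 of 85 cases (83 adjusted over the list alone, adjusted p = 0.368 with an estimated correlation), with Rpl3 at 1.52 ± 0.11. Of the Lin28 and let-7 list 7 genes rose and 2 fell of 10 (7 and 2 adjusted over the list alone, adjusted p = 0.293 with an estimated correlation). Hmga2 was higher by 2.48 ± 0.25 and Lin28a, an RNA-binding repressor of let-7 maturation, was lower by 1.39 ± 0.35. Of 18 cardiac genes 13 fell and 1 rose (14 and 1 adjusted over the list alone, adjusted p = 0.712 with an estimated correlation), and of 20 skeletal muscle genes 12 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.712 with an estimated correlation), with Myh3 at -5.34 ± 0.66 and Myf5 at 1.48 ± 0.53 (adjusted p = 0.14 without preparation 5 and 0.118 without preparation 8). Myh6 was lower by 3.75 ± 0.78 over all days but stood at 0.07 in preparations 5 and 8. There the cardiac list mean went from 0.742 to 0.471 in 5 and from 1.062 to 1.473 in 8 and the skeletal muscle list mean from 1.341 to 1.357 and from 1.281 to 1.426, while both lists fell in WT1, WT2 and WT3. The test called 12733 genes, 6475 higher and 6258 lower, so that 50.9% were higher, and 39.4% at a 2-fold minimum. Within the WT-titled preparations the count was 11786 and within preparations 5 and 8 it was 11681.

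Levels of the E2F family differed between the gates. The gates also differed in marker genes of cell types, so phase and the cells a gate holds cannot be told apart in these comparisons. Among the sorted fractions, E2f1, E2f2, E2f3, E2f6, E2f7, E2f8 and both E-type cyclins had their highest mean level in G1-S. E2f3, E2f7 and E2f8 were highest there in 4 of 5 preparations and E2f6 in only 3. In WT2 E2f6 stood at 73.8 CPM in G1-S and 86.2 CPM in S-G2-M, and in preparation 8 at 74.5 and 75.6 CPM. E2f1 (ENSMUSG00000027490.17, chromosome 2 from 154559407 to 154569892, minus strand) stood at 18.2 ± 3.16 CPM in G0, 45.7 ± 14.3 CPM in G1, 65.6 ± 10.6 CPM in G1-S and 36.6 ± 5.61 CPM in S-G2-M (mean ± SD, n = 5). It rose by 1.30 ± 0.16 from G0 to G1 (adjusted p = 7.45e-07) and by 0.55 ± 0.15 from G1 to G1-S (adjusted p = 0.0131), then fell by 0.82 ± 0.15 in S-G2-M (adjusted p = 0.000914). E2f2 rose by 1.67 ± 0.31 and 1.60 ± 0.30 and fell by 0.96 ± 0.29 over the same steps. Unsorted cells held more E2f2 than G1-S in preparations 5 (151.6 against 53.2 CPM) and 8 (136 against 54.5 CPM). In the WT-titled preparations they held less than G1-S. The atypical members E2f7 and E2f8 rose by 1.83 ± 0.20 and 2.18 ± 0.24 from G1 to G1-S, and their changes to S-G2-M did not pass the test (-0.49 ± 0.19, adjusted p = 0.077, and -0.53 ± 0.23, adjusted p = 0.125). E2f3 rose by 0.92 ± 0.09 and 0.79 ± 0.09 over the first steps, with -0.09 ± 0.09 afterwards (adjusted p = 0.539). E2f4 and E2f5, members known to act in repressor complexes, were highest in S-G2-M among the sorted fractions. There E2f4 rose by 0.39 ± 0.10 and E2f5 by 0.47 ± 0.12 above G1-S. Unsorted cells held more E2f4 than S-G2-M in preparations 5 (98.1 against 59.5 CPM) and 8 (106.5 against 61.8 CPM). They also held more in WT1 and WT3, but less in WT2 (62.8 against 64.6 CPM). Leaving out 1 preparation ended some of these calls: E2f1 from G1 to G1-S without preparation 5 (adjusted p = 0.101) or 8 (adjusted p = 0.0903), the fall of E2f2 without WT1 (adjusted p = 0.0914), WT2 (adjusted p = 0.104) or WT3 (adjusted p = 0.0913), the rise of E2f4 without preparation 5 (adjusted p = 0.0573) and that of E2f5 without WT2 (adjusted p = 0.0698). Over the WT-titled preparations alone E2f7 fell by 0.88 from G1-S to S-G2-M (adjusted p = 0.00192). E2f6 rose by 0.58 ± 0.10 from G1 to G1-S, and its change from G0 to G1 did not pass the test (0.12 ± 0.10, adjusted p = 0.358). As a list, the 17 E2F, DP and pocket protein genes had 10 risen from G0 to G1 (10 adjusted over the list alone, adjusted p = 0.0681 with an estimated correlation), 11 risen from G1 to G1-S (11 risen and 1 fallen adjusted over the list alone, adjusted p = 0.0102 with an estimated correlation), and 4 risen and 2 fallen from G1-S to S-G2-M (5 and 4 adjusted over the list alone), where the list test gave an adjusted p of 0.46. From G0 to S-G2-M 14 rose and Rb1 fell, by 0.85 ± 0.18 (14 and 1 adjusted over the list alone, adjusted p = 0.0109 with an estimated correlation). Cdkn1a did not pass the test from G0 to G1 (-0.18 ± 0.29, adjusted p = 0.668) or from G1 to G1-S (0.16 ± 0.29, adjusted p = 0.762) and was 1.53 ± 0.30 lower in S-G2-M than in G0. Cdkn1b fell by 0.29 ± 0.10 from G0 to G1, a call that ended without WT3 (adjusted p = 0.0826), preparation 5 (adjusted p = 0.12) or preparation 8 (adjusted p = 0.156).

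By the sorted fraction of highest mean level, a description without a test, 38 of 39 G2/M genes and 58 of 66 histone genes were highest in S-G2-M. Highest in G1-S were 20 of 23 licensing genes, 23 of 31 DNA synthesis genes, 12 of 19 recombination genes and 6 of 9 G1 cyclin genes. The G2/M genes had the same highest fraction in all 5 preparations in 38 cases, the licensing genes in 17 and the histone genes in 32.

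**Figure D3:**
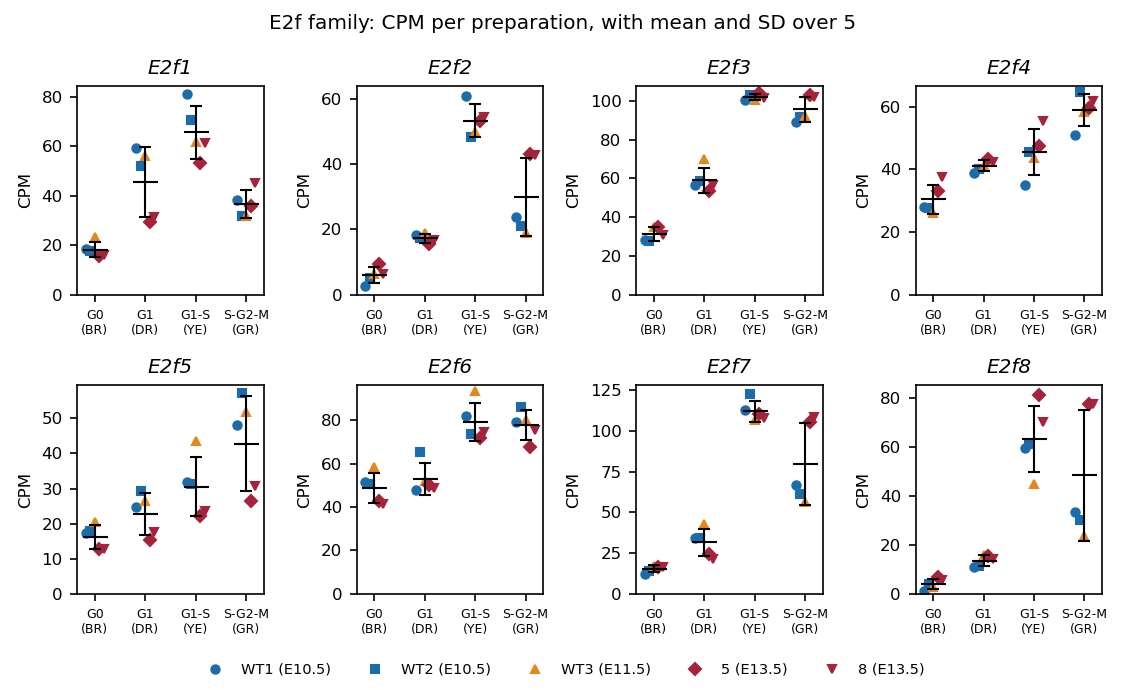
CPM (vertical axes, from 0) of E2f1 to E2f8 in the 4 sorted fractions (horizontal axes), with 1 point per preparation and black marks for the mean and SD over 5 preparations. E2f1, E2f2, E2f7 and E2f8 have their highest mean in G1-S, and E2f4 in S-G2-M at 59.0 CPM.

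The mean of the 4 sorted fractions, weighted equally, was set against the unsorted cells. Blood genes were lower after sorting, and most liver, macrophage and proliferation genes were lower in this mean. All 19 erythroid genes fell (19 adjusted over the list alone; median -5.17), and the call held with an estimated correlation (adjusted p = 0.00184). Hbb-y, an embryonic beta globin (ENSMUSG00000052187.4, chromosome 7 from 103851749 to 103853216, minus strand), fell by 6.08 ± 0.28 (SE, n = 5; adjusted p = 2.21e-13), with 14550 ± 4170 CPM in unsorted cells and 48.1 ± 15.1 CPM in S-G2-M (mean ± SD, n = 5). Hba-x fell by 6.06 ± 0.29, Hbb-bh1 by 5.85 ± 0.34 and Slc4a1, the anion exchanger of red cells, by 5.39 ± 0.36. Macrophage genes fell in 15 of 16 cases (15 adjusted over the list alone, adjusted p = 0.0215 with an estimated correlation), with Fcgr3 at -2.43 ± 0.18, and all 14 hepatocyte genes fell (14 adjusted over the list alone, adjusted p = 0.486 with an estimated correlation), with Afp at -3.39 ± 0.53. For these 2 lists as well the mean depends on the equal weights. The macrophage list mean was higher in G1-S than in unsorted cells in all 5 preparations (4.38 against 4.016 in preparation 5 and 2.565 against 2.493 in WT1), and the hepatocyte list mean in preparations 5 (6.481 against 5.728), 8 (6.091 against 5.365) and WT3 (1.978 against 1.778). All 39 G2/M genes (adjusted p = 0.0493 with an estimated correlation) and 64 of 66 histone genes (adjusted p = 0.0214 with an estimated correlation) were lower in the sorted mean, Hmmr by 2.62 ± 0.19 and Hist1h2bh by 2.48 ± 0.14, with the same counts adjusted over the list alone. Unsorted cells stood above all 4 fractions in all 5 preparations for 0 of the G2/M genes and 0 of the histone genes, against 19 of 19 erythroid genes, so for such genes too the mean depends on those weights. Licensing genes fell in 22 of 23 cases (23 adjusted over the list alone, adjusted p = 0.306 with an estimated correlation), DNA synthesis genes in 30 of 31 (30 adjusted over the list alone, adjusted p = 0.306 with an estimated correlation) and recombination genes in 16 of 19 (16 adjusted over the list alone, adjusted p = 0.486 with an estimated correlation). G1 cyclin genes fell in 7 of 9 cases (8 adjusted over the list alone, adjusted p = 0.345 with an estimated correlation) and E2F family genes in 9 of 17 (9 adjusted over the list alone, adjusted p = 0.248 with an estimated correlation). E2f2 was at -1.79 ± 0.21, with -1.08 in the WT-titled preparations and -2.52 in preparations 5 and 8, and E2f4 was at -0.89 ± 0.08. Ribosomal protein genes fell in 68 of 85 cases and rose in 2 (68 and 2 adjusted over the list alone, adjusted p = 0.293 with an estimated correlation). Rpl39 was at -1.17 ± 0.12. Of the dissociation response genes 14 were lower after sorting (14 adjusted over the list alone, adjusted p = 0.575 with an estimated correlation). Hspa1b was at -1.14 ± 0.15. Of 16 p53 target genes 8 fell and 1 rose (8 and 1 adjusted over the list alone, adjusted p = 0.525 with an estimated correlation). Phlda3 was at -0.96 ± 0.13 and Zmat3 at 0.63 ± 0.09. The largest rise among the genes named by rule was that of AC131743.1 (1.55 ± 0.30), a transcript that the annotation classes as TEC, a model still to be tested by experiment. E2f3 (-0.08 ± 0.07, adjusted p = 0.359) and Cdkn1a (0.02 ± 0.23, adjusted p = 0.95) did not pass the test over all days, and in preparations 5 and 8 they stood at 0.24 (adjusted p = 0.00316) and -0.43 (adjusted p = 0.0308). Cardiac genes were lower in 10 of 18 cases and higher in 1 (11 and 1 adjusted over the list alone), with an adjusted p of 0.0515, 0.0194 when preparation was a block and 0.755 with an estimated correlation. Over all genes 4569 were higher and 6754 lower in the sorted mean, so that 40.4% were higher, against 49.3% with RLE factors and 50.9% with DESeq2. At a 2-fold minimum the balance turned, with 1925 higher and 1210 lower (61.4% higher). The count was 7037 within the WT-titled preparations, 12713 within preparations 5 and 8, and 7518 without WT3, whose unsorted library alone, left out, gave 7911.

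The unsorted libraries of E13.5 were compared with those of E10.5 to describe the embryo by day, with n = 2 libraries at each day. The 1 library of E11.5 had its own mean in the model and entered no comparison. Most cartilage, liver and matrix genes were higher at E13.5 and 6 of 10 genes of the Lin28 and let-7 list were lower, while no list call of these 4 held with an estimated correlation. Cartilage genes rose in 12 of 13 cases (13 adjusted over the list alone, adjusted p = 0.122 with an estimated correlation), with Matn1 at 8.59 ± 0.34 (SE; adjusted p = 2.36e-05), Matn4 at 7.15 ± 0.23 and Acan, aggrecan, at 7.05 ± 0.30. All 15 hepatocyte genes rose (15 adjusted over the list alone, adjusted p = 0.345 with an estimated correlation), with Alb, albumin (ENSMUSG00000029368.10, chromosome 5 from 90460897 to 90476602, plus strand), at 6.05 ± 0.38. Mesenchyme and matrix genes rose in 19 of 21 cases (19 adjusted over the list alone, adjusted p = 0.386 with an estimated correlation), with Dcn at 3.79 ± 0.40, and macrophage genes in 14 of 16 (15 adjusted over the list alone, adjusted p = 0.47 with an estimated correlation), with Lyz2 at 3.21 ± 0.27. Globins switched in type: Hbb-bt and Hbb-bs, adult beta globins, rose by 5.18 ± 0.61 and 5.01 ± 0.39, Hbb-bh1 fell by 5.61 ± 0.42, and Hbb-y did not pass the test (0.40 ± 0.40, adjusted p = 0.441). The erythroid list had 15 genes risen and 1 fallen of 19 (16 and 1 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation). The Lin28 and let-7 list had 6 of 10 genes fallen (8 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation). Lin28a (ENSMUSG00000050966.9, chromosome 4 from 134003330 to 134018841, minus strand) fell by 4.94 ± 0.38, with means of 63.2 CPM at E10.5, 126 CPM in the 1 library of E11.5 and 2.04 CPM at E13.5. Lin28b fell by 2.22 ± 0.25, and Hmga2 was at -0.49 ± 0.19 (adjusted p = 0.0661). Epithelial genes rose in 5 of 15 cases and fell in 1 (5 and 1 adjusted over the list alone, adjusted p = 0.767 with an estimated correlation), with Krt15 at 4.57 ± 0.36, and skeletal muscle genes rose in 8 of 20 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.629 with an estimated correlation). Tnnc2 was at 5.29 ± 0.67, with 74% of its exon length under exons of the other strand. Of 6 CDK inhibitor genes 4 rose (4 adjusted over the list alone, adjusted p = 0.345 with an estimated correlation), Cdkn1c by 2.35 ± 0.16 (30.6% of its exon length under exons of the other strand). Dissociation response genes rose in 18 of 22 cases (18 adjusted over the list alone, adjusted p = 0.393 with an estimated correlation), Nr4a1 by 2.83 ± 0.22.

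Part of the replication genes and most recombination genes were lower at E13.5, and no list call of these held with an estimated correlation. Licensing genes fell in 14 of 23 cases (1 rose and 14 fell adjusted over the list alone, adjusted p = 0.767 with an estimated correlation), with Cdc45 at -0.90 ± 0.15, and recombination genes in 17 of 19 (18 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation). DNA synthesis genes fell in 16 of 31 cases and rose in 1 (17 and 1 adjusted over the list alone, adjusted p = 0.829 with an estimated correlation). The gene that rose was Fen1 (3.73 ± 0.16), with 84.2% of its exon length under exons of the other strand. Histone genes rose in 24 of 66 cases and fell in 11 (25 and 12 adjusted over the list alone, adjusted p = 0.698 with an estimated correlation), with a median change of 0.07 and a mean of 0.98. The largest rises in that list were those of Hist2h3b (ENSMUSG00000074403.2, chromosome 3 from 96268654 to 96269141, plus strand) and Hist2h2bb, both fully under exons of the other strand and at or near 0 counts in each WT-titled library, so that no fold is given. Ribosomal protein genes fell in 36 of 86 cases and rose in 6 (36 and 6 adjusted over the list alone, adjusted p = 0.713 with an estimated correlation), and mitochondrially encoded genes rose in 10 of 18 and fell in 4 (10 and 5 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation). Other large rises were Rmrp, an RNA of a ribonuclease complex (8.70 ± 0.26; 45.8% of its exon length under other-strand exons), Gnas (5.16 ± 0.24; 22.0%), Ftl1 (5.54 ± 0.25; 26.5%) and Jund (3.83 ± 0.19; 52.6%), and large falls included Igdcc3 (-3.54 ± 0.14) and Arg1, arginase (-4.01 ± 0.33). Over all genes 5598 were higher and 5718 lower of 24129 tested, so that 49.5% were higher, against 44.6% with RLE factors and 43.8% at a 2-fold minimum. Only genes without a gene body on the other strand, an alternative chosen after the data were seen, gave 6014 calls and turned the balance, with 3370 higher and 2644 lower (56.0% higher). Leaving out preparation 5 gave 6564 and leaving out preparation 8 gave 6382. All E13.5 libraries were of preparations 5 and 8 and all E10.5 libraries of WT1 and WT2. The day and the preparation set therefore cannot be told apart for any gene. The sets also differed in which overlapping genes had counts.

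The last comparison asked whether the change from G0 to S-G2-M itself differed between E13.5 and E10.5. Part of the muscle, cartilage and neuronal genes fell less, or rose, at E13.5. Neuronal genes had a higher difference in 12 of 24 cases and a lower one in 2 (17 and 2 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation), with Nefl at 4.32 ± 0.30 (SE, n = 2 preparations at each day; adjusted p = 1.18e-07). Skeletal muscle genes were higher in 10 of 20 cases (13 adjusted over the list alone, adjusted p = 0.0724 with an estimated correlation), with Ttn at 4.57 ± 0.80, and cardiac genes in 8 of 18 with 1 lower (13 and 1 adjusted over the list alone, adjusted p = 0.29 with an estimated correlation), with Myh6 at 5.08 ± 1.34. Cartilage genes were higher in 7 of 13 cases and lower in 1, which held with an estimated correlation (7 and 1 adjusted over the list alone; adjusted p = 0.0158). Cnmd, chondromodulin (ENSMUSG00000022025.13, chromosome 14 from 79637690 to 79662170, minus strand), led them at 6.72 ± 0.44. Of 6 CDK inhibitor genes 3 were higher (3 adjusted over the list alone), and this call too held with an estimated correlation (adjusted p = 0.0102). Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, gave 1.83 ± 0.19, Cdkn2d 1.67 ± 0.24 and Cdkn1a 1.67 ± 0.41. Exons of the other strand cover 30.6% of Cdkn1c and 32.8% of Nefl. Cdkn1c averaged 283 CPM in G0 and 92.8 CPM in S-G2-M at E10.5, and 533 CPM and 620 CPM at E13.5. Mesenchyme and matrix genes were lower in 7 of 21 cases (9 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Prrx1 was at -3.19 ± 0.20 and Twist1 at -2.64 ± 0.40. G1 cyclin genes were lower in 5 of 9 cases (6 adjusted over the list alone, adjusted p = 0.356 with an estimated correlation). Ccne1 was at -1.02 ± 0.26. Epithelial genes were higher in 5 of 15 cases (9 adjusted over the list alone, adjusted p = 0.343 with an estimated correlation), with Trp63 at 2.08 ± 0.51, and endothelial genes in 1 of 15, Robo4 (1 adjusted over the list alone, adjusted p = 0.745 with an estimated correlation). Licensing genes were lower in 2 of 23 cases (1 higher and 6 lower adjusted over the list alone, adjusted p = 0.673 with an estimated correlation), DNA synthesis genes in 4 of 31 (14 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), ribosomal protein genes in 3 of 85 (0 adjusted over the list alone, adjusted p = 0.713 with an estimated correlation), and G2/M genes were higher in 4 of 39 (6 adjusted over the list alone, adjusted p = 0.712 with an estimated correlation). Cdc25b was at 1.55 ± 0.28. Of 10 genes of the Lin28 and let-7 list 3 were lower (3 adjusted over the list alone), with an adjusted p of 0.0624, 0.0215 when preparation was a block and 0.673 with an estimated correlation. Pcna stood at -0.87 (adjusted p = 0.0518), and at -0.89 with the block (adjusted p = 0.00783), and E2f8 at -0.01 (adjusted p = 1) but at 0.74 without WT1 (adjusted p = 0.0256). Outside the lists, Igf1 gave -3.96 ± 0.28 and Meox1 -3.97 ± 0.49. The test called 996 genes with a higher and 1040 with a lower difference, 2036 in all, and 3380 with preparation as a block. Of these 2036 calls 48.9% were higher, against 55.3% with RLE factors and 54.3% at a 2-fold minimum. Without preparation 5 it called 231 genes and without preparation 8 it called 253, while without WT1 and WT2 the counts were 4283 and 3597.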

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

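Among 130 sets of 5 libraries of 1 fraction, each examined for a library far from the other 4, 3 stood out, and chance gives about 1 in 20 such sets. The G0 library of WT1 had 27.65 M counts against 19.6 to 21.4 M in the other G0 libraries, with a gap of 0.785 of the range. Ccna2, cyclin A2, stood at 7.04 CPM in that same library against 11.6 to 13.9 CPM (gap 0.731). E2f6 stood at 65.4 CPM in the G1 library of WT2 against 47.7 to 52.1 CPM (gap 0.718).

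For 41 of the named genes the change from G0 to S-G2-M differed between E13.5 and E10.5 by the test of the difference itself (edgeR quasi-likelihood test, n = 2 preparations at each day). Part of these genes were named because they passed this same test, so the count does not measure how common such differences were. Over all genes the test called 2036 of 23506 (8.7%). The values below are log2 differences, E13.5 minus E10.5. The largest was that of the cartilage gene Cnmd at 6.72 (adjusted p = 1.18e-07), which was at -5.31 at E10.5 and at 1.38 at E13.5. Col11a2, another cartilage gene, gave 3.45, and Sox9, a regulator of cartilage formation, gave -0.97. Muscle genes gave 5.08 for Myh6, 4.69 for Myh7, 4.68 for Mymk, a factor of myoblast fusion, 4.57 for Ttn, 3.92 for Myh3 and 3.76 for Myf5. Tbx5, a heart and limb factor, gave -1.52. Neuronal genes went both ways, with 4.32 for Nefl, 4.13 for Nefm and 2.60 for Stmn2, against -1.67 for Mapt and -1.83 for Pou4f1. Grem1, gene of a secreted BMP antagonist, gave -3.90. Robo4 of endothelial cells gave 3.39, and the epithelial genes Trp63 and Krt14 gave 2.08 and 2.06.

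Of the cell cycle genes, the CDK inhibitors Cdkn1c, Cdkn2d and Cdkn1a gave 1.83, 1.67 and 1.67. Cdkn1c was lower in S-G2-M than in G0 at E10.5 (-1.62) and stood at 0.22 at E13.5. Cdc25b and Prc1 of the G2/M list gave 1.55 and 1.34. Genes of replication and of the G1 cyclin list rose less at E13.5, with -0.94 for Mcm4, -0.98 for Mcm5, -0.95 for Chaf1b, -1.10 for Prim1, -0.97 for Cdk2 and -1.02 for Ccne1. The ribosomal protein list gave -0.75 for Rpl12 and -0.81 for Rpl7l1. Lower differences were also those of genes outside these groups, with -1.81 for Hmga2, -2.64 for Twist1, -3.19 for Prrx1, -3.87 for Barx1, -3.97 for Meox1 and -3.97 for Dmrt2. Igf1, a growth factor, gave -3.96 and turned from 2.81 at E10.5 to -1.18 at E13.5. Preparations of E13.5 also differed from the others in title and in which overlapping genes had counts, so the day and the preparation set cannot be told apart.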

How the results depend on the processing

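Every alternative below was fixed before the data were examined except 3: genes without a gene body on the other strand, Gm26917 and Gm42418 left out, and the unsorted library of WT3 left out. DESeq2, RLE factors, no filter on low counts, abundant genes left out and equal depth kept each count of changed genes within 1.5 times. A 2-fold minimum gave 3553 genes for G1 minus G0, 1418 for G1-S minus G1, 1559 for S-G2-M minus G1-S, 6454 for S-G2-M minus G0 and 3135 for sorted minus unsorted. Genes without a gene body on the other strand, which are fewer, gave 5687 for G1 minus G0, 2942 for G1-S minus G1, 8224 for S-G2-M minus G0, 6014 for the days and 1310 for the day difference. Parts of libraries entered as separate samples, which treats technical parts as replicates, gave 10639 for G1-S minus G1, 10748 for S-G2-M minus G1-S and 6949 for the day difference. The WT-titled preparations gave 2233 for G1-S minus G1, 2708 for S-G2-M minus G1-S and 7037 for sorted minus unsorted. Preparations 5 and 8 gave 8476 for G1-S minus G1. With 1 preparation left out, the counts ran from 6845 to 7815 for G1 minus G0, 2529 to 5187 for G1-S minus G1 and 2430 to 3278 for S-G2-M minus G1-S. They ran from 11181 to 11884 for S-G2-M minus G0, 7518 to 12422 for sorted minus unsorted, 6382 to 16534 for the days and 231 to 4283 for the day difference. Where this leaves 1 library at a day, that library is assumed to vary like the others. Beyond fewer genes or samples, the cause was not tested. Fraction of highest expression stayed as it was for 197 to 207 of 210 cell cycle genes with 1 preparation left out.

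Preparation as a block gave 3380 genes for the day difference, kept all 2036 called without it, and left the other counts within 1.5 times. With the block 91 of 144 list tests passed against 88 without it, with 0 lost and 3 gained. The p53 targets turned direction in the day difference without passing (adjusted p = 0.944). Of the named genes Hba-x and Pcna changed their call in 1 comparison each, and no other call changed. With an estimated correlation 23 of 104 list calls held. Over 383 results for named genes and all alternatives, 6144 values kept direction and side of the threshold, 293 no longer passed, 49 newly passed and 52 turned direction. Leaving out preparations 5 and 8 in turn ended 48 and 50 calls, and the 2-fold minimum 74.

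The turned values, for which the cause was not tested, were mostly of genes that did not pass the test. In preparations 5 and 8 these were Myh6 (0.06) and Cnmd (2.27, adjusted p = 2.25e-05) in G1 minus G0, Cdkn1c (0.07) in G1-S minus G1, and E2f3 (0.01) and E2f8 (0.04) in S-G2-M minus G1-S. They were also Myh6 (0.07) and Cdkn1c (0.17) in S-G2-M minus G0, and E2f3 (0.24, adjusted p = 0.00316), Cdkn1a (-0.43, adjusted p = 0.0308) and E2f1 (0.12) in sorted minus unsorted. In the WT-titled preparations they were Cdkn1c (-0.05) in G1 minus G0, Cdkn1b (-0.03) in G1-S minus G1, and E2f7 (-0.10) and Cdkn1c (0.01) in sorted minus unsorted. With parts not summed they were Cdkn1c (-0.02) in G1 minus G0, Cdkn1b (-0.04) in G1-S minus G1, Cdkn1c (0.04) in sorted minus unsorted, and E2f3 (0.01) and E2f8 (0.04) in the day difference. Without the unsorted library of WT3, sorted minus unsorted gave 0.00 for E2f3, -0.01 for Cdkn1a and 0.02 for Cdkn1c. E2f6 in S-G2-M minus G1-S was 0.01 both without other-strand genes and without Gm26917 and Gm42418, and the latter gave -0.02 for Cdt1 in the day difference. In that comparison DESeq2 gave 0.02 for Gmnn, 0.01 for E2f3 and 0.07 for E2f8, and RLE factors gave 0.01, 0.01 and 0.06. Abundant genes left out gave 0.04 for E2f8.

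With 1 preparation left out, the values that turned are given with the range over all 5. Cdkn1b in G1-S minus G1 ran from -0.01 (without 8) to 0.18, and E2f6 in S-G2-M minus G1-S from -0.09 to 0.07 (WT3). Hbb-y between the days ran from -0.12 (WT2) to 1.02. In sorted minus unsorted E2f3 ran from -0.12 to 0.03 (WT3) and Cdkn1c from -0.16 to 0.04 (WT3). Cdkn1a ran from -0.08 (WT2), with -0.03 (WT1), to 0.26. In the day difference Cdt1 ran from -0.12 (8), with -0.06 (WT3), to 0.13, and Gmnn from -0.47 to 0.28 (WT1). E2f3 ran from -0.18 to 0.05 (5), with 0.00 (WT2), and E2f2 from -0.77 to 0.37 (WT1), with 0.16 (5). Ccna2 ran from -0.15 (WT2) to 0.45, Mki67 from -1.29 to 0.10 (WT1) and Ccnb1 from -0.23 (WT2) to 0.92. E2f6 ran from -0.06 (8) to 0.20. E2f8 ran from -1.12 to 0.74 (WT1, adjusted p = 0.0256), with 0.20 (5). Depth was 14.7 M counts or more in each library. Equal depth ended 3 of 380 results for named genes.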

Other observations

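The tests of the marker genes in G1-S, of strand and of transcript classes below were chosen after the results were seen, while the test of the unsorted sample as a mixture and the regrouping of libraries were set before. Atypical E2F genes stood apart by preparation in S-G2-M. E2f7 was at 105 and 108 CPM in that fraction of preparations 5 and 8 and at 56.4 to 67.0 CPM in the WT-titled ones, while in G1-S it was at 107 to 122 CPM in all 5. E2f8 was at 77.9 and 77.6 CPM in S-G2-M of preparations 5 and 8 and at 23.7 to 33.7 CPM in the others, with 45.0 to 81.4 CPM in G1-S. The difference of this step between days was not tested.

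Neural progenitor genes peaked in different gates. Among the sorted fractions their mean log2 CPM over the list was highest in G1 in WT1 (6.05), WT2 (5.84) and WT3 (5.54), where S-G2-M stood at 5.60, 5.46 and 5.37. In preparations 5 and 8 it was highest in S-G2-M (5.86 and 6.08) with G1 at 5.08 and 5.12, and this difference was not tested. Of the sorted fractions endothelial genes were highest in G1-S in all 5 preparations, with 13 or 14 of 15 members above every other sorted fraction.

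Marker genes of macrophages, cardiac muscle, endothelium and hepatocytes had their highest list level among the 4 sorted fractions in G1-S in all 5 preparations, which makes 4 of 11 cell type lists. Random pairs of a red and a green cell sorted together could raise a marker in G1-S only to the highest other fraction's level. Cell types that pair by preference could exceed it, and which cells pair was not measured. The median over list members exceeded the level of the highest other fraction by 1.17 or more for macrophages and by 0.33 or more for cardiac muscle. For hepatocytes at E13.5 the excess was 5.30 or more. These values argue against random pairs only, and pairs formed by preference stay open. The lists were tested because they were highest in G1-S, so some excess was likely beforehand. For hepatocytes at E10.5 and E11.5 the excess was -0.14, 0.27 and 1.23, which decides nothing. A first test over all days was undecided (lowest -0.14), and the separation by day was made after those values were seen. Carry-over of unsorted cells is argued against by a ratio of G1-S to unsorted that was higher for hepatocyte than for erythroid genes by at least 2.65 on the log2 scale, and own fluorescence of such cells may place them in the gate but stays open, as does a biological difference, because no fluorescence record was used here.

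Preparations 5 and 8 and the WT-titled preparations differed in which overlapping genes had counts. Of 56 genes above 1 CPM on average in 5 and 8 and at 3 counts or fewer in each WT-titled library, 85.7% lay with most of their exon length under exons of the other strand, against 0.7% of genes expressed in both, a ratio of 122.4. Of 784 genes with the opposite pattern 85.7% lay with most of their exon length inside gene bodies of the other strand, against 7.8%. A candidate explanation is that reads were counted by strand in preparations 5 and 8 and without strand in the others, and a ratio this far above 1 argues against genes switched on between the days as the whole cause. The 369 calls between the days with a rise over 16-fold lay mostly under exons of the other strand in 31.7% of cases, against 1.7% of all genes tested. The 1844 with a fall over 16-fold had most of their exon length inside gene bodies of the other strand in 81.8%, against 16.9% of all genes tested.

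The unsorted libraries were not mixtures of the sorted ones: 1192 genes lay above all 4 fractions in all 5 preparations and 613 below, where chance gives 7.5 on each side. All 19 erythroid and 42 of 85 ribosomal protein genes were among those above, and 186 of 1749 TEC transcripts, annotated models still to be tested by experiment, were among those below. Erythroid RNA diluting all other RNA alike is argued against, because the median change of such transcripts exceeded that of ribosomal protein genes by 1.83 on the log2 scale. This covers an equal dilution only. Which cells the ribosomal protein RNA came from was not measured, so a part of erythroid cells in its fall stays open. More unspliced or nuclear RNA in sorted libraries stays open: these transcripts were higher after sorting in 5 of 5 preparations (lowest 0.06) and ribosomal protein genes in 0, but a set of 6 nuclear RNAs, which should rise in each, was higher in 4 (lowest -0.28), with 3 of its genes past the test. Cells outside the 4 gates also stay open, since no gate record was used here.

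Regrouping the libraries at random gave counts below the real ones. In 1 of 100 splits, the real one, as many genes were called, for each of 5 comparisons, which argues against a random grouping of the libraries. The median of the other splits was 0 in each comparison. A false split leaves the real difference of the gates in the spread, so the real split was likely to lead, and its lead says nothing on what separates the gates. The real counts and the highest of the other splits were 8540 and 4284 for G1 minus G0, 4444 and 2078 for G1-S minus G1, 4087 and 89 for S-G2-M minus G1-S, 12733 and 6982 for S-G2-M minus G0, and 11323 and 8656 for sorted minus unsorted. These highest splits kept 4 of 5 libraries on their real side, or 3 of 5 for the last comparison. Among splits with 1 library of each preparation on a side, 14 in each phase comparison and 5 for sorted cells with the real one counted, the highest others were 554, 2078, 3, 5388 and 43.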
